A study of Nicotiana attenuata with 6 samples.

How the data were processed

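Leaf RNA of *Nicotiana attenuata* was measured in 3 wild type and 3 irJAZh samples on a custom one-colour array, with 1 array per sample and Cy3 as the dye. The platform holds 45220 features, of which 43803 are not controls, for probes of 60 bases; 30 probes are spotted 10 times. All samples were labelled as wounded and treated with oral secretions of *Manduca sexta*, and harvest is given as 2 h in titles and source names but as 1 h in a description field. The samples are labelled as independent experiments, and p-values measure only the spread between these samples.

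The intensity values are the processed signals in the scanner files as deposited, made by Agilent Feature Extraction 9.5 per the authors' notes. Per the file headers, spatial detrending, multiplicative detrending and surrogate values for signals not above background were on and the global background adjustment was off, and these intensities were not scaled between arrays. The ratio values of the deposited value table are on a linear scale with 3 digits and were averaged over the spots of a probe. The authors do not state their scaling step; from the values, each column is the processed signal divided by that array's 75th percentile over all features, controls included. Its column medians were 0.109, 0.104 and 0.106 for wild type and 0.104, 0.105 and 0.101 for irJAZh, so the values are neither centred per gene nor a contrast between samples, and none of scale, centring and direction was left open. The number of arrays limits the precision. Between 0 and 6 spots per array carried an outlier mark and none was saturated.

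The processed intensities were taken from the deposited scanner files, spots with a non-uniformity or population outlier mark were set to missing, and spots of a probe were averaged. Values were expressed as log2 minus the 75th percentile of each array over non-control probes. A probe was tested if it was well above background on at least 3 of the 6 arrays, whatever their genotype, which left 24577 probes (20443 of them named, for 13120 entries). Probes well above background on all arrays numbered 21849, and those on none 16094. Genotypes were compared with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8), with a two-sided moderated test and Benjamini-Hochberg adjustment over all tested probes, at an adjusted p under 0.05. The prior degrees of freedom were 2.68 and the residual ones 4. Where no array of a genotype was well above background, the fold is given as a bound against a background limit. This limit is the lowest signal of any probe well above background on that array. A probe's own limit can be higher, so the bounds given as "at least" are approximate and the change can be smaller. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.

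Samples of the same replicate number shared a slide. Over tested probes, deviations from the genotype mean correlated at 0.22, 0.31 and 0.13 between samples of the same number and at -0.25 to 0.021 between others, so a fit with the slide as a block is given beside the results it changes. Tested on simulated data with 24570 probes and no slide effect, the fit without a block recovered 68.7%, 97% and 100% of changes of log2 1, 2 and 3 with 7 false calls, and the fit with the block 31.3%, 97.1% and 100% with 9 false calls. A simulated list shifted by 0.5 was called and no other list was. The simulated genes were drawn independently, so this does not test false list calls from genes that vary together.

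Probe names give a contig and the Swiss-Prot entry name of its best match, without the strength of the match. Of all probes 33639 carry such a name and 14107 of these name a plant entry. Several contigs can share an entry and can be fragments of 1 gene or paralogs. Contigs named for different entries can also belong to 1 gene, so the genes counted in the lists are entry names. No contig was found in the available reference table (0 matches), so no genome positions are given. No probe is named for JAZh; JAZF1_PONAB is an unrelated zinc-finger entry.

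The 26 gene lists were fixed by protein name before the data were examined, as were the tests, the alternatives and the rule for named genes. They were translated to entry names after the names but before any value had been seen. Some members are matches to bacterial entries, and the ethylene response factor list includes AP2-like proteins. Lists were tested with camera (preset correlation 0.01) on the brightest probe of each entry, with Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation and fry were run beside it. The lists cover JAZ repressors, jasmonate biosynthesis and turnover, proteinase inhibitors, other anti-herbivore proteins, isoprenoids, terpene synthases, phenolamides, phenylpropanoids, nicotine, ethylene, salicylate, reactive oxygen, glutathione S-transferases, cell death, 3 transcription factor families, photosynthesis, ribosomes, heat shock, cell walls, and trichome, vascular, dividing and guard cell markers.

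The rule for named genes took JAZh (in its absence all TIFY probes), the 10 largest increases and 10 largest decreases among changed genes with a known function and non-overlapping groups, the 2 members of each list with the smallest p, and genes that earlier work on this line concerns. What counted as an uncharacterized name was settled after the largest changes had been seen. Alternatives covered normexp background correction with an offset of 50, quantile and median scaling, the filter, the block and the moderation of variances. Array weights, the deposited value table, thresholds, list tests and leaving out each array were also covered. Cyclic loess normalization and a looser threshold with the block were added after the data were seen. Control spots and per-spot background columns were not used in the comparison itself.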

Results

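Gene expression was measured in leaves of *Nicotiana attenuata*, a wild tobacco, from 3 wild type samples and 3 samples of irJAZh plants. The label irJAZh is not spelled out and is read here as a line silenced by an inverted repeat for JAZh, a jasmonate ZIM-domain (TIFY) protein of the family that represses jasmonate responses. All 6 leaf samples had been wounded and treated with 20 µL of diluted oral secretions (1 part in 5) of larvae of the hawkmoth *Manduca sexta*. The sample titles give harvest 2 h later, while the description field gives 1 h, and the 2 h of the titles is used here. Each sample was hybridised to 1 array with 43803 spots that are not controls, and 33639 probes carry the entry name of a best protein match, often from another species. On average 54.1% ± 1.04 (SD, n = 3) of probes were well above background on the wild type arrays and 57.7% ± 2.11 (SD, n = 3) on the irJAZh arrays (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). The 75th percentile of the signal was 95.9 ± 8.71 in wild type and 142 ± 19.5 in irJAZh before scaling (SD, n = 3; exact permutation p = 0.1). Within a genotype, arrays correlated at 0.978 to 0.994 across probes, and between genotypes at 0.971 to 0.982. The number of arrays limits the precision of every value below, and n is 3 arrays per genotype throughout.

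The comparison asked how silencing JAZh alters the leaf transcriptome after simulated herbivory. In irJAZh leaves 6 of 19 proteinase inhibitor genes, 6 of 21 plastid isoprenoid genes and 5 of 15 ethylene synthesis genes rose, and none of these lists passed with an estimated correlation (adjusted p = 0.392). Contigs whose best matches are a floral defensin, a tapetum protein and a benzoate methyltransferase were among those that rose most. Each was well above background on all wild type arrays too. Among the largest decreases were single contigs named for sabinene, cineole and vinorine synthase, while brighter contigs of the latter 2 names rose, and a pair of TIFY genes fell while another rose. Of 24577 probes tested, 335 were higher and 340 lower in irJAZh leaves (limma, Benjamini-Hochberg adjusted p under 0.05). Over 2-fold, 192 were higher and 151 lower, and under normexp background correction 83 were higher and 14 lower. All 675 changed probes had non-overlapping groups, which fixes the same sign on each of the 3 slides, where 1 wild type and 1 irJAZh sample were hybridised. Among all tested probes, 6878 (28%) had non-overlapping groups, where chance gives 10%. The series' own description counts 480 genes over 2-fold without naming a test or a filter. Probes, which are not the same unit as genes, differed over 2-fold in the mean in 820 cases here, 491 higher and 329 lower. That count was 443 with probes well above background on all 6 arrays (244 higher, 199 lower), 110 under normexp (95 higher, 15 lower) and 2025 without a filter on dim probes (787 higher, 1238 lower). With the slide as a block, which leaves 2 residual degrees of freedom in place of 4, 8 probes passed (5 higher, 3 lower), all among the 675, and 671 of the 675 had an adjusted p under 0.1. The 8 were BAMT_ANTMA, AB13G_ARATH, MTNN_GEOSW, SSS_SALOF and 4 contigs without a name, chosen for mention after their values were seen: Na_454_29023 and Na_454_40030 rose, and Na_454_18702 and Na_454_31269 fell. The count of 675 became 50 without wild type replicate 2, 56 without wild type replicate 3, 383 without irJAZh replicate 1, 31 without irJAZh replicate 2 and 52 without irJAZh replicate 3. Of these reduced counts, those of 50, 56, 31 and 52 lay wholly over 2-fold, against 343 with all arrays. Of the 51 changed results for genes named by rule below, 35 lost their call without wild type replicate 2, 34 without wild type replicate 3, 16 without irJAZh replicate 1, 41 without irJAZh replicate 2, 37 without irJAZh replicate 3 and 5 without wild type replicate 1.

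No probe is named for JAZh, so the silencing of the target could not be read from these arrays and the genotype labels were not checked in this way. In its place, the 16 tested probes named for TIFY proteins were examined on each array. TIFY 11A (TI11A_ARATH, Na_454_11296) fell by 1.82 ± 0.18 on the log2 scale (SE), from 4.47 ± 0.33 in wild type to 2.65 ± 0.09 in irJAZh (SD; limma adjusted p = 0.0125). TIFY 11B (TI11B_ARATH, Na_454_10092) fell by 1.73 ± 0.11 (adjusted p = 0.00534), with values of -0.23, -0.26 and -0.24 on the wild type arrays and -2.10, -1.84 and -1.97 on the irJAZh arrays. Both probes named TIFY 5A rose, by 2.20 ± 0.18 (Na_454_20188, adjusted p = 0.009, well above background on 2 of 3 wild type arrays) and 1.84 ± 0.14 (Na_454_13225, adjusted p = 0.00725). The other 12 TIFY probes did not pass, and the nearest was TIFY 9 (TIF9_ARATH, Na_454_01883) with a difference of 0.94 ± 0.19 (adjusted p = 0.0558). Whether either falling probe belongs to JAZh is not known from the probe names. With the slide as a block the adjusted p of the 4 changed probes was 0.0561 to 0.0565, and their within-slide differences were -2.11 to -1.59 for the falling and 1.68 to 2.52 for the rising ones.

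**Figure D1:**
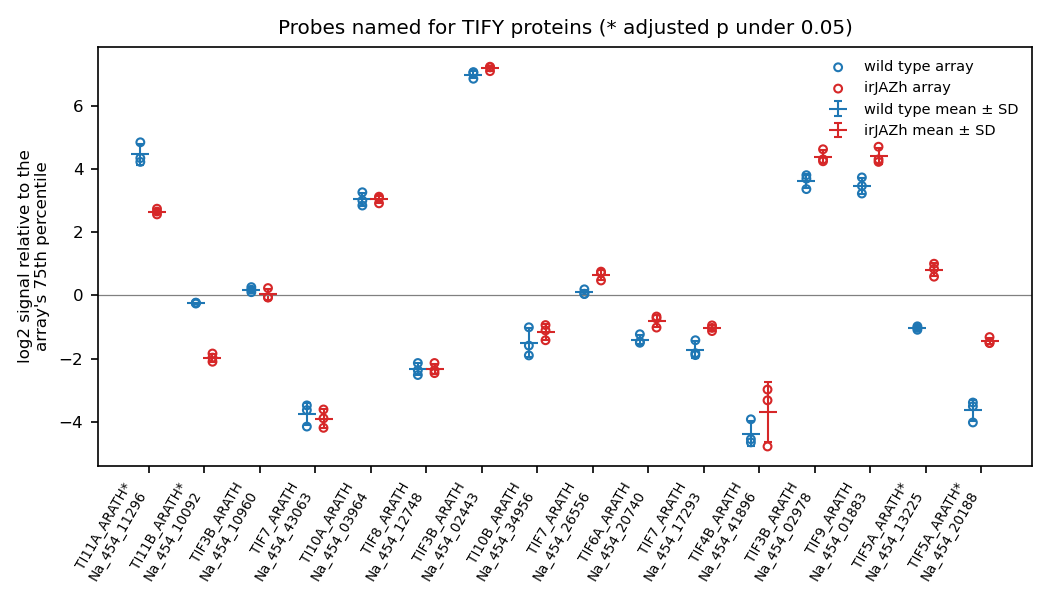
Signal of the 16 tested probes named for TIFY proteins, as log2 relative to each array's 75th percentile, on 3 wild type arrays and 3 irJAZh arrays (circles), with the mean and SD of each genotype. Probes are ordered by the difference irJAZh minus wild type, from TI11A_ARATH (-1.82) to TIF5A_ARATH (2.20), and the 4 with an asterisk passed an adjusted p under 0.05.

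Of the 10 named genes with the largest measured increases, the 6 well above background on all arrays rose by log2 2.55 to 4.94. A contig named for a floral defensin (DEF2_PETHY, Na_454_14379), a type of small antimicrobial protein, rose 30.8-fold (log2 4.94 ± 0.66 SE, adjusted p = 0.0227). Without irJAZh replicate 2 its difference was 4.35 (adjusted p = 0.0753). A second contig of that name (Na_454_02035) rose by 3.93 ± 0.32 (adjusted p = 0.00836), from a log2 value of 3.35 in wild type. TAP1 (TAP1_ANTMA, Na_454_04122), named for a tapetum protein of snapdragon, rose 9.16-fold (3.20 ± 0.29, adjusted p = 0.0113) from a log2 value of 4.50 in wild type, while 2 other contigs of that name did not pass. A benzoate carboxyl methyltransferase (BAMT_ANTMA, Na_454_08320), an enzyme type that makes floral scent esters, rose 7.68-fold (2.94 ± 0.15, adjusted p = 0.00345). An ABC transporter of subfamily G (AB13G_ARATH, Na_454_36276) rose by 2.70 ± 0.12 (adjusted p = 0.00182). A U-box ubiquitin ligase (PUB26_ARATH, Na_454_37170) rose by 2.90 ± 0.38 and a methylthioadenosine nucleosidase (MTNN_GEOSW, Na_454_17962) by 2.55 ± 0.29. A probe whose best match is a yeast RNA helicase (DBP3_PICGU, Na_454_32684) rose (adjusted p = 0.0142) by an amount left open, since it was well above background on only 1 wild type array. Other contigs named BAMT_ANTMA, AB13G_ARATH, BCS1_DANRE and C7D95_MENSP did not pass and lay at -0.51 to 0.02, except an AB13G_ARATH contig (Na_454_14557, well above background on 2 of 3 wild type arrays) that rose by 0.81 ± 0.12. A further 3 were not well above background on any wild type array and have only a lower bound: a limonene hydroxylase of the P450 71D family (C7D95_MENSP, at least 2.23-fold higher), a mitochondrial carnitine carrier (MCAT_ARATH, at least 2.20-fold) and the mitochondrial chaperone BCS1 (BCS1_DANRE, at least 4.11-fold). With the slide as a block, the adjusted p stayed under 0.05 for BAMT_ANTMA (0.0389), MTNN_GEOSW (0.0389) and AB13G_ARATH (0.0496) and was 0.0565 to 0.0825 for the other 7. The within-slide differences of the 6 genes well above background on all arrays were 1.63 to 6.14.

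Of the 10 named genes with the largest measured decreases, 4 were well above background on all arrays and fell by 1.84 to 3.34 on the log2 scale. The size of the fall is open for 2 that were well above background on only 1 irJAZh array, and the other 4 have only a lower bound, so that their rank is not known. A pair of these 4 are monoterpene synthases, enzymes of leaf and trichome volatiles. Sabinene synthase (SSS_SALOF, Na_454_05117) was at least 5.30-fold lower (adjusted p = 0.00739) and cineole synthase (SCS_SALOF, Na_454_11047) at least 3.58-fold lower (adjusted p = 0.00836). The contigs named SCS_SALOF disagree, since the brighter one (Na_454_03027) rose by 1.95 ± 0.26 (adjusted p = 0.0227). A pair of BAHD-type acyltransferases fell, vinorine synthase (VINSY_RAUSE, Na_454_03244) by 3.34 ± 0.29 (adjusted p = 0.00982) and BAHD1_ARATH (Na_454_33648, adjusted p = 0.0219) by an amount left open, as it was well above background on only 1 irJAZh array. Of the 6 contigs named VINSY_RAUSE, a brighter one (Na_454_03083) rose by 1.15 ± 0.18 (adjusted p = 0.0322), and the other 4 lay above 0 and did not pass. The other 4 contigs named BAHD1_ARATH lay at -0.32 to 1.01 and did not pass. A pair of beta-galactosidases fell, BGAL_ASPOF (Na_454_00222) by 1.84 ± 0.22 and BGAL9_ORYSJ (Na_454_04690, adjusted p = 0.0174) by an amount left open for the same reason, while the other contig of each name lay above 0 and did not pass (0.50 and 0.25). The ethylene response factor ERF92_ARATH (Na_454_29205) fell by 2.08 ± 0.25 (adjusted p = 0.0174), while a brighter contig of that name (Na_454_28397) lay at 0.99 ± 0.28 and did not pass (adjusted p = 0.111). The remaining 3 best match a rat transmembrane protein (TM45B_RAT, at least 4.49-fold lower), a rice entry (KNOSD_ORYSJ, at least 1.94-fold lower) and an archaeal transducer (HTR1_HALSA, which fell by 1.98 ± 0.37). A brighter contig named KNOSD_ORYSJ (Na_454_01766) also fell, by 1.00 ± 0.16 (adjusted p = 0.0339). The contigs Na_454_23886 and Na_454_05918 of that name lay at -0.80 and -0.74 and did not pass (adjusted p = 0.0622 and 0.0809). With the slide as a block, the adjusted p stayed under 0.05 for SSS_SALOF (0.0389) and was 0.0561 to 0.0989 for the other 9, with within-slide differences of -3.63 to -0.88 for the 4 well above background on all arrays.

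**Figure D2:**
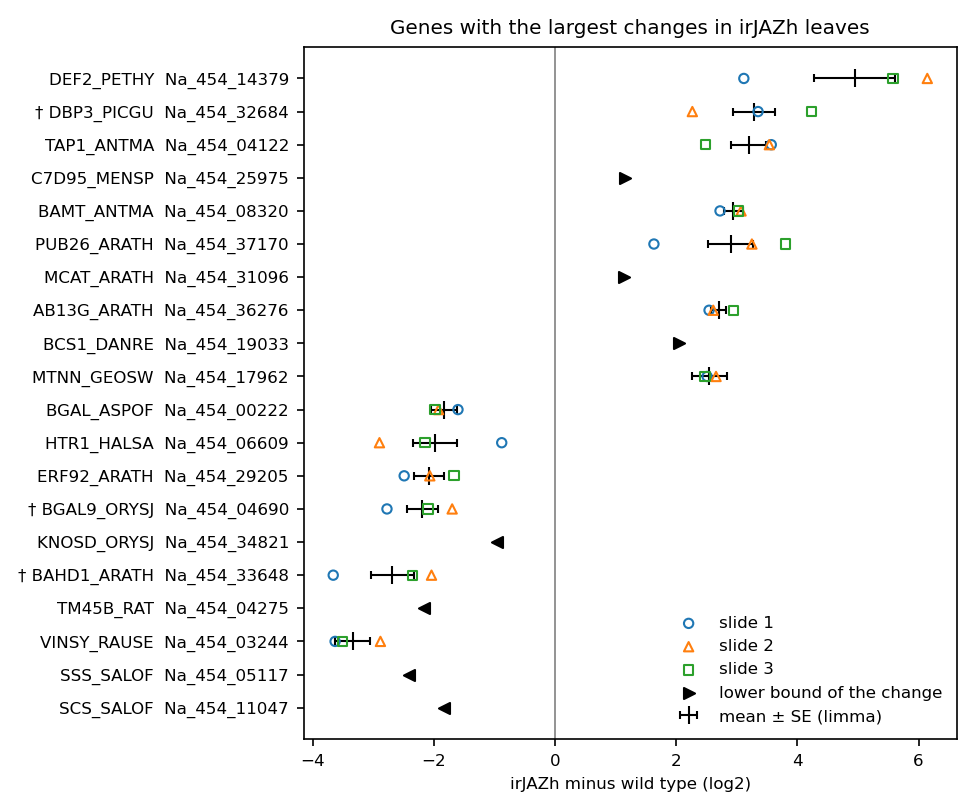
Difference irJAZh minus wild type on the log2 scale for the 20 named genes with the largest changes, with 1 open symbol per slide and the mean and standard error of the limma fit in black, or a black triangle at the lower bound of the change for genes not well above background in 1 genotype (dagger: well above background on only 1 array of a genotype). The genes were chosen to have non-overlapping groups, so all slides lie on 1 side of 0, and DEF2_PETHY (4.94) and PUB26_ARATH (2.90) vary widely between slides.

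Of 26 gene lists fixed before the data were examined, 8 were shifted relative to the other genes, all upward (camera with a preset correlation of 0.01, adjusted p under 0.05), and none passed with an estimated correlation (adjusted p = 0.392 to 0.538 for these 8). The list members were taken as 1 probe per entry name, the brightest. Plastid isoprenoid and diterpene glycoside synthesis, which supplies the defensive diterpene glycosides of this species, had the highest median, 0.62 over 21 genes (camera adjusted p = 7.45e-05, and adjusted p = 0.392 with an estimated correlation). Of these, 6 rose, 15 did not pass and none fell, and adjusted over the list alone 11 rose and 2 fell. All 6 belong to the methylerythritol phosphate pathway: deoxyxylulose phosphate synthase (DXS_MAGSA, 1.38 ± 0.17, adjusted p = 0.0174, and DXS_OCHA4, 1.52 ± 0.23), ISPE_PARUW (0.99 ± 0.14, adjusted p = 0.0239), ISPE_ARATH, ISPG_CHLMU and ISPH_THEEB. Within the slides the list median was 0.35, 0.71 and 0.38, and with the slide as a block the camera adjusted p was 0.000758.

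Proteinase inhibitors, which impair digestion in feeding larvae, had a median of 0.19 over 19 genes (camera adjusted p = 0.00713, and adjusted p = 0.392 with an estimated correlation). Of these, 6 rose, 13 did not pass and none fell, with the same counts adjusted over the list alone. The proteinase inhibitor 2 IP2X_SOLTU (Na_454_02256) rose 3.26-fold (1.71 ± 0.18, adjusted p = 0.0127), the carboxypeptidase inhibitor MCPI_SOLTU (Na_454_01378) rose 2.44-fold (1.29 ± 0.12, adjusted p = 0.0105), and the trypsin proteinase inhibitor ITR1_NICSY (Na_454_02881) rose 3.78-fold (1.92 ± 0.31, adjusted p = 0.0322), while 2 dimmer contigs of that last name (Na_454_32917 and Na_454_18667) did not pass. The list median within the slides was 0.21, 0.22 and 0.20, and its adjusted p with the block was 0.0158.

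Hormone lists moved in part. Ethylene synthesis had a median of 0.51 over 15 genes (camera adjusted p = 0.0151, and adjusted p = 0.392 with an estimated correlation), and 5 rose, 10 did not pass and none fell (8 rose and 3 fell adjusted over the list alone). These were the ACC oxidases ACCO2_MALDO (1.20 ± 0.10, adjusted p = 0.00982) and ACCO2_SOLLC (0.96 ± 0.18) and the ACC synthases 1A11_PRUMU (1.13 ± 0.12, adjusted p = 0.0147), 1A1C_TOBAC and 1A1C_SOYBN. Jasmonate turnover had a median of 0.26 over 10 genes (camera adjusted p = 0.0128, and adjusted p = 0.392 with an estimated correlation), and 3 rose and 7 did not pass (4 rose and 1 fell adjusted over the list alone). The 3 included an amidohydrolase (ILL1_ARATH, 0.95 ± 0.13, adjusted p = 0.0242) and a jasmonate methyltransferase (JMT_BRARP, 0.76 ± 0.14). They also included a cytochrome P450 listed by its family name (C94A2_VICSA, 0.89 ± 0.15, adjusted p = 0.0377). Whether this P450 acts on jasmonates is not known from its name. Within the slides the medians were 0.47, 0.62 and 0.43 for ethylene synthesis and 0.22, 0.19 and 0.39 for jasmonate turnover, and with the block the adjusted p was 0.0481 and 0.0158. Jasmonate biosynthesis did not pass as a list (median 0.11 over 9 genes, camera adjusted p = 0.216) and none of its genes passed (1 rose and 1 fell adjusted over the list alone). Its nearest members were allene oxide synthase (CP74_LINUS, -0.93 ± 0.24, adjusted p = 0.091) and a jasmonoyl amino acid synthetase (GH35_ORYSJ, 0.92 ± 0.24, adjusted p = 0.0966). The JAZ repressor list did not pass either (median 0.34 over 11 genes, adjusted p = 0.189), with 1 gene risen, 2 fallen and 8 not passed, and 4 risen and 2 fallen adjusted over the list alone. This list took in every tested TIFY entry, among them TIF8_ARATH and TIF4B_ARATH, which are TIFY proteins but not JAZ repressors.

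Phenylpropanoid and flavonoid synthesis had a median of 0.13 over 39 genes (camera adjusted p = 0.00881, and adjusted p = 0.392 with an estimated correlation), of which 3 rose and 36 did not pass (13 rose and 3 fell adjusted over the list alone). These were a phenylalanine ammonia-lyase (PALY_HELAN, 0.86 ± 0.12, adjusted p = 0.0239), a caffeoyl-CoA methyltransferase (CAMT3_ARATH, 0.88 ± 0.14, adjusted p = 0.0307) and a chalcone isomerase (CF1B2_SOYBN, 0.78 ± 0.13). The within-slide medians were 0.23, 0.21 and 0.16, and the adjusted p with the block was 0.0158. Ribosomal proteins had a median of 0.20 over 99 genes (adjusted p = 6.48e-05, and adjusted p = 0.538 with an estimated correlation), with 79 above 0 but only 1 passing by itself, also adjusted over the list alone (RK24_TOBAC, not well above background in wild type, at least 1.01-fold higher, and at -0.06 under normexp background correction). Their within-slide medians were 0.03, 0.24 and 0.26, and the adjusted p with the block was 0.000149.

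Markers of other leaf cell types were listed to show shifts in tissue make-up. Guard cell and epidermis markers had a median of 0.13 over 39 genes (camera adjusted p = 0.0151, and adjusted p = 0.538 with an estimated correlation). Of them 2 rose, the GDSL lipases GDL40_ARATH (1.02 ± 0.14, adjusted p = 0.0239) and GDL46_ARATH (0.99 ± 0.15, adjusted p = 0.0287), and 37 did not pass (6 rose adjusted over the list alone). These lipases were listed by their family name, so their rise does not by itself show a shift in tissue make-up. Dividing cell markers had a median of 0.12 over 27 genes (camera adjusted p = 0.0457, and adjusted p = 0.538 with an estimated correlation), of which histone H2B_GOSHI rose (1.18 ± 0.19, adjusted p = 0.0328) and 26 did not pass (2 rose adjusted over the list alone). The within-slide medians were 0.22, 0.04 and 0.15 for the first list and 0.04, 0.14 and 0.18 for the second, and with the block the adjusted p was 0.0203 and 0.0341. The first call was lost without wild type replicate 3 (adjusted p = 0.111) or irJAZh replicate 1 (0.263), and the second without wild type replicate 1 (0.0962), wild type replicate 3 (0.102), irJAZh replicate 2 (0.0926) or irJAZh replicate 3 (0.121), and under quantile normalization (0.169). The dividing cell median lay within the central range of random lists matched on signal (-0.09 to 0.14). The lists of mesophyll (photosynthesis, adjusted p = 0.216), glandular trichome (0.216), vascular (0.47) and root nicotine genes (0.739) did not pass. Among their members, the oxygen-evolving protein PSBO_WHEAT fell by 0.79 ± 0.12 (adjusted p = 0.0275), the lipid transfer protein NLTP_MAIZE fell by 1.03 ± 0.17 (adjusted p = 0.0329), the phloem protein P2A15_ARATH rose by 2.08 ± 0.12 (adjusted p = 0.00393) and P2A08_ARATH fell by 0.70 ± 0.12 (adjusted p = 0.0363). Their other members, 48, 11, 29 and 7 genes, did not pass.

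**Figure D3:**
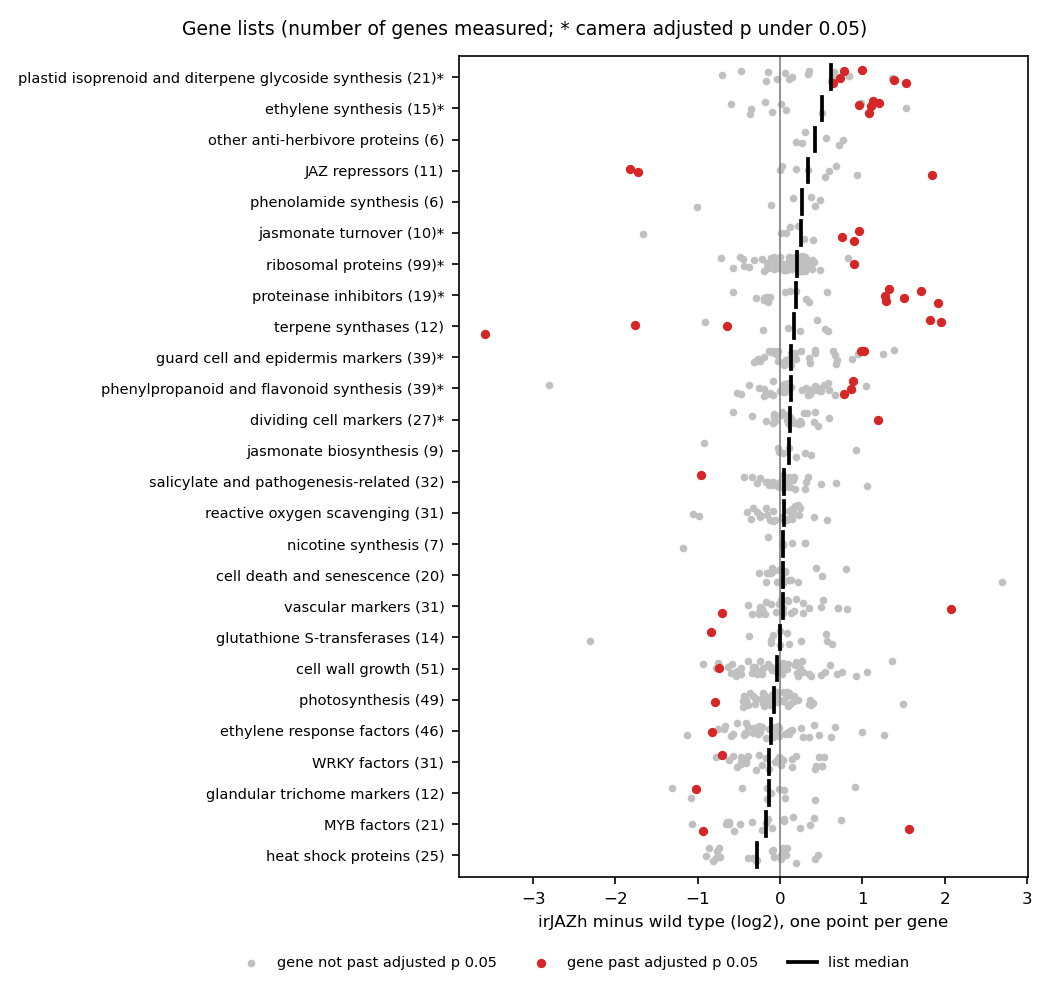
Difference irJAZh minus wild type on the log2 scale for every measured gene of the 26 lists, with 1 point per gene (3 arrays per genotype), red where the gene passed an adjusted p under 0.05, and a black line at the list median, all as measured, also for genes above background in 1 genotype only. The 8 lists with an asterisk passed camera with a preset correlation, with medians from 0.12 to 0.62, and none of the 26 passed with an estimated correlation.

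Terpene synthases moved both ways: of 12 genes, 2 rose (SCS_SALOF by its brighter contig and ECS1_ARTAN, 1.82 ± 0.30), 3 fell (SSS_SALOF, DCS3_GOSAR by 1.76 ± 0.13 and LINS_ARATH by 0.65 ± 0.11) and 7 did not pass (camera adjusted p = 0.979). Adjusted over the list alone the counts were the same. The other anti-herbivore proteins lay above 0 in 6 of 6 genes but did not pass as a list (median 0.43, adjusted p = 0.0545), and no member passed. Without irJAZh replicate 1 this list passed (adjusted p = 0.019), as did photosynthesis (0.0309). Their nearest was the polyphenol oxidase PPOE_SOLLC (0.76 ± 0.21, adjusted p = 0.104). Phenolamide synthesis did not pass (median 0.27 over 6 genes, adjusted p = 0.451), with spermidine synthases at 0.49 ± 0.17 (SPD1_DATST, adjusted p = 0.178) and 0.42 ± 0.17 (SPD2_HYONI, adjusted p = 0.215), while a dimmer contig named SPD1_DATST (Na_454_01724) rose by 0.63 ± 0.12 (adjusted p = 0.0471). No transcription factor list passed: the adjusted p was 0.156 for WRKY factors, 0.216 for ethylene response factors and 0.189 for MYB factors. Of 31 WRKY genes 1 fell (WRK65_ARATH by 0.70 ± 0.12), and of 21 MYB genes 1 rose (MYB2_PHYPA, 1.57 ± 0.20) and 1 fell (MYB59_ARATH by 0.94 ± 0.13). Of the 46 genes in the ethylene response factor list 1 fell, the AP2-like SMZ_ARATH (by 0.82 ± 0.15). This list holds ERF92_ARATH by its brighter contig, which did not pass, and not by the dimmer one that fell by 2.08 (Na_454_29205). Adjusted over the list alone, 4 WRKY genes fell, 3 members of the ethylene response factor list rose and 3 fell, and 2 MYB genes rose and 6 fell. Heat shock proteins had the lowest median, -0.28 over 25 genes (adjusted p = 0.216), with -0.25, -0.29 and -0.31 within the slides. With the slide as a block this list passed (adjusted p = 0.0481), although none of its genes passed and the adjusted p was 0.522 with the block and an estimated correlation. It also passed without wild type replicate 1 (0.0146) and without irJAZh replicate 2 (0.047).

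Genes that passed only when adjusted over their list alone were named after their values were seen. The TIFY genes TIF9_ARATH, TIF7_ARATH and TIF6A_ARATH were higher by 0.94, 0.55 and 0.60. In the isoprenoid list ISPG_SYNS9 (-0.70) and ISPD_CLOTE (-0.47) were lower. Both geranylgeranyl diphosphate synthases named GGPPS, GGR_ARATH (0.84), DXR_CYAA5 (0.65) and ISPE_CHLMU (by an amount left open, well above background on only 1 wild type array) were higher. In the flavonoid list the dihydroflavonol reductase DFRA_HORVU (by an amount left open, well above background on only 1 irJAZh array), the flavanone hydroxylase FL3H_MATIN (-0.53) and the flavonol synthase FLS_MALDO (-0.48) were lower, against 10 genes that were higher (0.37 to 1.04). Among ACC oxidases ACCO_TOBAC, ACCO_ACTDE and ACCO_PERAE were lower (-0.59, -0.36 and -0.35) and ACCO1_SOLLC and ACCO_MUSAC higher (1.53 and 0.51), as was the ACC synthase 1A12_SOLLC (0.99). The difference of ACCO1_SOLLC varied between slides 1, 2 and 3 (2.73, 0.76 and 1.09), with an SD of 1.23 in wild type and 0.17 in irJAZh. The P450 C94A1_VICSA was lower by an amount left open (well above background on 2 wild type arrays and 1 irJAZh array), and the amidohydrolase ILL5_ARATH lay at 0.40. Guard cell and epidermis members were GDL9_ARATH, GDL10_ARATH and KCS13_ARATH (0.87 to 1.25) and WAXS8_ARATH, which was not well above background in wild type and at least 1.30-fold higher, and a histone H3 (H32_TOBAC) lay at 0.59. The WRKY factors WRK11_ARATH, WRK16_ARATH and WRK26_ARATH lay at -0.57 to -0.48. CRF4_ARATH, ERF2_TOBAC and TOE3_ARATH were higher (0.61, 1.26 and 0.67) and PLET2_ARATH and EF118_ARATH lower (-0.68 and -0.75), MYB44_ARATH was higher (0.73), and MYB06_ANTMA, MYB15_ANTMA, MB3R1_ARATH and MYB5_ARATH were lower (-0.66 to -0.49), as was MYB05_ANTMA (-1.07, well above background on 2 of 3 irJAZh arrays). The pectinesterases PME44_ARATH, PME_DAUCA and PME38_ARATH and the xyloglucan enzyme XTH22_ARATH were higher (0.60 to 1.36), the expansin-like EXLA3_ARATH lower (-0.63), and GSTX1_SOLTU higher (0.63).

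Few genes tied to salicylate, oxidative stress and cell death passed. Of 32 salicylate and pathogenesis-related genes, PR4B_TOBAC fell by 0.96 ± 0.12 (adjusted p = 0.0207) and 31 did not pass (list adjusted p = 0.716). Of 14 glutathione S-transferases, GSTX1_NICPL fell by 0.84 ± 0.10 (adjusted p = 0.0174) and 13 did not pass (list adjusted p = 0.919; 1 rose and 1 fell adjusted over the list alone). Of 51 cell wall growth genes, EXTN_SORBI, an extensin, fell by 0.74 ± 0.13 (adjusted p = 0.0417) and 50 did not pass (list adjusted p = 0.716; 4 rose and 2 fell adjusted over the list alone). None of 31 reactive oxygen scavenging genes passed (list adjusted p = 0.993), with catalase CATA1_TOBAC nearest at -1.06 ± 0.24 (adjusted p = 0.0715). Within the slides CATA1_TOBAC lay at -1.08, -1.04 and -1.06. With the slide as a block its limma adjusted p was 0.0565, no higher than that of the changed TIFY 11A probe (0.0565), so a fall of this catalase is not excluded. None of 20 cell death and senescence genes passed (list adjusted p = 0.459), and vacuolar processing enzymes lay at 0.51 ± 0.12 (VPEA_ARATH, adjusted p = 0.0733) and 2.70 ± 0.85 (VPEB_ARATH, adjusted p = 0.139, well above background on 2 of 3 wild type arrays). The latter rests on wild type replicate 3, without which it was 1.66, and was 3.42 without wild type replicate 2. Further list members with the smallest p that did not pass were VSPA_SOYBN (0.19), NADB_ECOLI (-1.18), NADC_METTH (0.30), NPR1_ARATH (-0.43), GPX4_TOBAC (0.41), PSBK_TOBAC (-0.45), RS23_FRAAN (0.39), HS154_ARATH (-0.75), HSP12_SOLPE (-0.75) and NLTP2_SOLPN (-1.31). In 4 lists the median, mean and test differed in sign: terpene synthases (median 0.17, mean -0.12, or -0.02 with SSS_SALOF at its bound, test downward), nicotine synthesis (0.04, -0.07, upward), reactive oxygen scavenging (0.05, -0.05, downward) and glutathione S-transferases (-0.003, -0.12, upward).

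Genes that earlier work on this line concerns were followed by their brightest probe, and dimmer contigs are named where their values differed, after these were seen. Geranylgeranyl diphosphate synthase, the precursor enzyme of diterpene glycosides, lay at 0.67 ± 0.14 (GGPPS_HEVBR, adjusted p = 0.0622) and 0.62 ± 0.13 (GGPPS_CATRO, adjusted p = 0.0576), and a dimmer contig of the latter name (Na_454_00621) rose by 1.30 ± 0.19 (adjusted p = 0.0274). Allene oxide synthase C74A2_ORYSJ lay at -0.02 ± 0.10 (adjusted p = 0.933), while a dimmer contig of that name (Na_454_01281) rose by 0.92 ± 0.14 (adjusted p = 0.0306). Allene oxide synthase C74A2_PARAR lay at 0.38 ± 0.16 (adjusted p = 0.228). Threonine dehydratases went both ways without passing, THD1_SOLTU at 0.55 ± 0.43 (adjusted p = 0.508), THD1_PASMU at 1.09 ± 0.40 (adjusted p = 0.188) and THD1_BURM1 at -0.38 ± 0.11 (adjusted p = 0.106), and putrescine methyltransferase PMT4_TOBAC at -0.14 ± 0.14 (adjusted p = 0.623). The catalases CATA1_NICPL, CATA2_NICPL and CATA3_NICPL lay at -0.24 ± 0.22, -0.99 ± 0.29 and 0.56 ± 0.23, and none passed. Within the slides they lay at -0.483 to 0.121, -1.085 to -0.836 and 0.377 to 0.716. With the slide as a block their limma adjusted p was 0.393, 0.0606 and 0.0937. Geranyllinalool synthase, lipoxygenase 3, MYB8 and MYC2 were not analysed here. With the slide as a block, each gene named here that changed without it, apart from those given above with a value under 0.05, had an adjusted p of 0.0561 to 0.0989.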

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

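Cyclic loess normalization and the block at a looser threshold were chosen after the data had been seen. The 675 changed probes became 665 under quantile normalization, 722 under median scaling, 915 with probes well above background on all 6 arrays, 686 from the value table and 752 under cyclic loess. They became 346 under normexp background correction (241 higher, 105 lower), 72 without a filter on dim probes, 8 with the slide as a block, 1040 with an intensity trend and robust moderation, 2517 with array weights and 1148 with the block and an intensity trend. Looser thresholds gave 1919 at an adjusted p under 0.1, 5206 at an unadjusted p under 0.05, and 1880 with the block at an adjusted p under 0.1. Leaving out 1 array gave 31 (without irJAZh replicate 2) to 759 (without wild type replicate 1). Fewer arrays leave fewer degrees of freedom, as does the block; for the other settings the cause was not tested.

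The 343 changed probes over 2-fold became 97 under normexp (83 higher, 14 lower), 72 without a filter (49 higher, 23 lower), 8 with the block and 696 with array weights, 31 to 464 without 1 array, and 302 to 394 elsewhere. The 820 probes over 2-fold in the mean became 110 under normexp (95 higher, 15 lower), 2025 without a filter (787 higher, 1238 lower, with a median of -0.15 over all probes) and 443 with probes well above background on all 6 arrays, where fewer probes are tested; they were 802 to 998 without 1 array. Normexp was run with an offset of 50 added to every signal, while array medians of the processed signal were 9.04 to 16.5. Such an offset compresses the differences of dim probes. Whether it accounts for the whole drop under normexp was not tested. The 8 lists became 0 with an estimated correlation, alone or with the block, and 6 to 11 under the other alternatives; fry for a change in either direction, which compares no list with other genes, passed 22.

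All 8 lists past the threshold kept their direction in each alternative for which a direction per list was kept, which leaves out cyclic loess and fry. Under cyclic loess 8 lists passed, 7 upward and 1 downward, so not all of the 8 upward calls were kept there, and which lists differed is not known. Of the 18 others, the anti-herbivore proteins passed under normexp (0.000763), without a filter (0.0478), on all 6 arrays (0.0425), with trend and robust moderation (0.0327) and with array weights (0.0219). JAZ repressors and jasmonate biosynthesis passed without a filter (0.0222 and 0.0478) and with all tested probes (0.0234 and 0.0199), and photosynthesis with array weights (0.0333).

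Lists that changed direction were all past no threshold either way, and the cause was not tested. Terpene synthases did so under normexp (adjusted p = 0.46), without a filter (0.71), on all 6 arrays (0.495), with trend and robust moderation (1) and with all tested probes (0.191), and without irJAZh replicate 3 (0.503 to 0.98 over the arrays left out). Reactive oxygen scavenging did so under normexp (0.61), median scaling (0.961), without a filter (0.634), on all 6 arrays (0.937), with all tested probes (0.542) and without wild type replicate 2 or 3 or irJAZh replicate 3 (0.879 to 0.971 over the arrays left out). Glutathione S-transferases did so under normexp (0.61), on all 6 arrays (0.56), with trend and robust moderation (1), array weights (0.837), all tested probes (0.917) and without wild type replicate 1 or irJAZh replicate 2 (0.34 to 0.971). Nicotine synthesis did so under normexp (0.696) and without wild type replicate 3 (0.416 to 0.96), salicylate genes without a filter (0.918) and without wild type replicate 3 or irJAZh replicate 1 (0.323 to 0.941), photosynthesis without a filter (0.974), and cell wall growth without wild type replicate 1 (0.383 to 0.975).

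Of the 51 results for named genes that had passed, RK24_TOBAC alone changed sign, under normexp (-0.0645). Genes that had not passed changed sign near 0. These were TIF8_ARATH (-0.0872), C74A2_ORYSJ (0.04) and C74A2_PARAR (-0.0352) under normexp, TI10A_ARATH under quantile normalization (-0.029) and TIF7_ARATH (Na_454_43063) with array weights (0.0136). Leaving out 1 array gave -0.0672 to 0.125 for TIF8_ARATH, -0.339 to 0.00522 for TIF7_ARATH, -0.0933 to 0.114 for TI10A_ARATH and -0.0721 to 0.0115 for C74A2_ORYSJ. The cause was not tested. The silencing of JAZh has no value under any alternative, as no probe bears its name. Signal over background limits 60 of the 675 calls, which are bounds (43 higher, 17 lower).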

Other observations

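In irJAZh leaves 4 of 14 probes for patatins, known from storage organs, were higher, and 5 of 38 probes for small auxin-induced proteins were lower, while the other probes of both families did not pass. The gene families in the next paragraph were picked after the largest changes had been seen, and the tests on them are hypotheses from the same data. Of the tests further on, cyclic loess normalization was chosen only after the result was seen.

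The SAUR proteins, small proteins induced by auxin in growing tissue, lay below 0 in most of 38 probes, with a median of -0.56. Of these 5 fell and 33 did not pass (camera adjusted p = 2.24e-07, and adjusted p = 0.0386 with an estimated correlation). All 5 bear the name AXX15_SOYBN, from Na_454_14987, which fell by 1.73 ± 0.19 (adjusted p = 0.0146, well above background on 2 of 3 irJAZh arrays), to Na_454_24453, which fell by 0.96 ± 0.11 (adjusted p = 0.0165), with Na_454_15400, Na_454_13550 and Na_454_42388 between. Patatins, lipid acyl hydrolases known as tuber storage proteins, had a median of 0.48 over 14 probes, and 4 rose and 10 did not pass (adjusted p = 0.033, and adjusted p = 0.645 with an estimated correlation). The 4 were PT2K3_SOLTU (Na_454_00365, 2.00 ± 0.22, adjusted p = 0.0142), PT2K4_SOLTU (1.86), PT3K1_SOLTU (Na_454_21689, 1.76) and PAT07_SOLTU (1.81). The other contigs named PT3K1_SOLTU lay at -0.39 to 0.12 and did not pass, among them the brightest patatin probe (Na_454_15471, 2.74 in wild type, difference -0.31). A dimmer contig named PT2K3_SOLTU (Na_454_17479) lay at 1.20 and did not pass. Of 31 probes for ABC transporters of subfamily G, 3 rose and 28 did not pass (adjusted p = 0.973): AB13G_ARATH by 2.70 (Na_454_36276) and 0.81 (Na_454_14557, well above background on 2 of 3 wild type arrays), and AB15G_ARATH (Na_454_40792) by 2.27 ± 0.13 (adjusted p = 0.00393). Of 17 probes for cytochromes P450 71D, terpene and sesquiterpene hydroxylases, 2 rose (C7D95_MENSP and C71D6_SOLCH, the latter by 2.20 ± 0.25), 1 fell (C71DI_MENSP, Na_454_24013, by 1.57 ± 0.16) and 14 did not pass (adjusted p = 0.973).

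The irJAZh arrays were brighter before scaling, and 675 probes changed between the genotypes. Of these calls 97.9% were kept with their sign under cyclic loess normalization, which removes shifts that depend on brightness, so such a shift is unlikely to be their whole cause. Normexp background correction, which compresses differences of dim probes, kept 253 of the 675 with their sign, so the calls of dim probes may rest on how background is handled. The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05: 1 of the 10, the real one, gave as many changed probes (675, highest other 0, with 207 to 1654 at an unadjusted p under 0.05 in limma), 1 of the 10 as many over 2-fold (343, highest other 0), and 1 of the 10 as many lists (8, highest other 5). Among the 3 other splits that also part every slide the highest was 0, 0 and 4, and the remaining splits part 1 slide each. A response to the genotype stays among the open explanations, and a difference in the amount or quality of labelled RNA between the genotypes was not tested otherwise.

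The ribosomal protein list lay above the other genes with a median of 0.20 over 99 genes. Its median was at percentile 100 of 10000 random gene lists matched on mean signal (their median 0.03, their central range -0.02 to 0.09). The matched genes were drawn independently, while the list had an estimated correlation of 0.29, so this range is too narrow and the percentile too high. Genes of like brightness had a median of only 0.03, so a shift that depends on probe brightness is unlikely to be the whole cause. Among the other 7 lists past the threshold the percentile was 98.7 to 100 for 6, but 94.7 for dividing cell markers, whose median of 0.12 lay within the matched range of -0.09 to 0.14. Only lists that had already passed on the same values were matched, so high percentiles add no separate support. For the ribosomal list, a biological difference between the genotypes and the correlation among its genes stay open. With an estimated correlation the list did not pass (camera adjusted p = 0.538). On slide 1 its median was 0.03, against 0.24 and 0.26 on the others.

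Genes named for flower proteins, DEF2_PETHY and TAP1_ANTMA, rose in irJAZh leaves. Wild type leaves already held their signal, at log2 values of -2.92 (Na_454_14379) and 3.35 (Na_454_02035) for DEF2_PETHY and 4.50 (Na_454_04122) for TAP1_ANTMA. These names are best matches, so whether the genes are particular to flowers is not known. If flower tissue in the irJAZh samples were the source of the rise, floral organ identity genes would be higher too. The 5 tested probes of that kind had a median log2 difference of -0.112 and none passed, and 21 of the 26 such probes on the array were above background on no irJAZh array. The 5 tested were above background on all wild type arrays, so a small share of flower tissue could be hidden in them, and the bound set for them beforehand (a median under 0.5) did not allow for that. The 21 others were above background on no irJAZh array and so give no sign of flower tissue. No flower sample was measured, so whether these probes would detect a small share is not known. Flower tissue and a change of these genes within leaf cells therefore cannot be told apart here.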
